A study of Mus musculus with 13 samples.

How the data were processed

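Pancreas from 8-week-old mice of 4 genotypes was measured by 3' tag RNA sequencing: wild type (3 mice), Nrf2 active in pancreatic cells (4), mutant Kras (3) and the 2 changes combined (3). Each library came from 1 mouse. Libraries were QuantSeq 3' FWD, made per the labels' protocols from total RNA and read on a NextSeq 500. The protocol text names liver as the dissected tissue, whereas the sample labels name pancreas. Acinar enzyme genes took 1.71% to 57.5% of assigned reads, and albumin (Alb) reached at most 16.2 normalised CPM.

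The deposited table held 1 signal value per gene and mouse, which the values themselves showed to be CPM (reads scaled to a fixed total over all gene rows), here not stored as a count. The genome build was GRCm38, per the submitters' processing notes. The aligner, the counting program, its use of strand, the annotation and the use of molecular barcodes were not given in the sources used here. The table held 47643 gene identifiers, of which 28025 had no read in any library and 19618 were detected. Besides the genes it held a total and 5 read classes, which were kept out of library sizes and tests. Reads outside annotated genes made up 5.70% to 37.4% of reads, and ambiguous reads 0% to 5.94%. Wild type replicate 3 had 0% ambiguous reads, the lowest value, and Kras+Nrf2 replicate 3 had the highest share outside genes.

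All values (100%) were whole multiples of 1 read within a tolerance of 0.001 reads, so whole reads were recovered from each column. Assigned reads per library ran from 798347 to 1526628. A gene with no read over a group was given a floor of 3 reads over that group, which was 1.53 CPM in wild type, 0.841 in Nrf2-active, 1.00 in Kras-mutant and 0.221 in Kras+Nrf2 pancreas. Fold changes called "at least" use this floor. The floors cover counting error only, not differences between mice.

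The design fixed before the data were examined planned edgeR for counts and limma for a table that did not hold counts. The deposited unit was not counts, so limma 3.58.1 was the reported test. It was run with a mean trend and robust variances on log2(CPM + 1) after TMM scaling by edgeR 4.0.16. This scale understates the fold change of genes with few reads. All 13 libraries entered 1 fit with 4 group means. Genes were kept by filterByExpr with a minimum count of 10, which left 4635 genes. A gene was past the test at a Benjamini-Hochberg adjusted p below 0.05 over these genes. The median total degrees of freedom was 20.26. TMM factors ran from 0.554 to 5.33. Acinar enzyme genes with Gm42418 took most reads of every library except Kras+Nrf2 replicate 3, where they took 1.71% and 16.7%. The edgeR tests on the recovered reads and DESeq2 1.42.0 were run as alternatives.

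Comparisons were each single genotype against wild type, the combined genotype against each of the other 3, and the interaction of Kras and Nrf2. Gene lists were written from textbook knowledge before the data were examined. There were 29 lists. Sex-linked genes served as a check only and were not tested as a list. The other lists with at least 3 tested genes numbered 25. They were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison. Counts of list genes cover tested members only, for example 18 of 39 metaplasia, 7 of 40 cell cycle and 7 of 34 interferon genes. A gene could pass the read filter through a single group, as Timp1, Cxcl5 and Ctse did through Kras+Nrf2. For such genes a rise in that group was partly set by the filter. Camera was repeated with the correlation estimated from the libraries, and fry was run as a further test.

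Named genes followed a rule fixed before the data were examined. Nfe2l2, Kras, Keap1, Ezh2 and Nqo1 were always named. For each comparison the rule added the 6 largest rises and 6 largest falls among genes past the test with a mean of at least 10 CPM and no overlap between groups. Predicted genes, immunoglobulin segments and ribosomal or mitochondrial pseudogenes were left out of these. It further added up to 3 genes with the smallest p from each list past its test, and up to 6 interaction genes with the smallest adjusted p. Members of a list could be named where the list was described. Identifiers were matched to symbols and positions with GENCODE M21. Of the 71 named genes, 20 overlap a gene on the opposite strand, so their values depend on how strand was used in counting. Reads of close relatives, such as the trypsinogen genes, may also be divided among them by alignment.

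The test was tested on simulated data drawn from the means and depths of the real libraries, with 200 of the 4635 genes changed. The simulated libraries kept the TMM factors of the real ones, so these rates do not test the scaling. For Nrf2-active vs wild type, limma recovered 10.4% of 2-fold, 59.7% of 4-fold and 87.9% of 8-fold changes, and 12 of 117 calls were false. For Kras-mutant vs wild type it recovered 5.97%, 53.7% and 78.8%, and 11 of 103 calls were false. For Kras+Nrf2 vs wild type it recovered 2.99%, 35.8% and 86.4%, and 3 of 86 calls were false.

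Settings fixed in advance were DESeq2 and its size factors, a stricter filter and no filter, a fit on the compared groups only, a variance fit that was not robust, exclusion of acinar enzyme genes from the libraries, and each library left out in turn. Settings added after the data were seen were edgeR, the deposited CPM without TMM, scaling without Gm42418 and mitochondrial rRNA, pseudocounts of 0.5 and 4, and 3 settings on libraries. The library settings were a term for the number in the sample titles (9 libraries up to 16, the others 36 and above), the 9 low-numbered libraries alone, and the exclusion of Kras+Nrf2 replicate 3 and wild type replicate 3. The labels do not say what the title numbers mean. All 3 wild-type libraries were low-numbered. The high-numbered ones were Nrf2-active replicates 2 and 4, Kras-mutant replicate 3 and Kras+Nrf2 replicate 3. The number class is therefore partly confounded with every comparison against wild type. The low-numbered set also leaves out Kras+Nrf2 replicate 3, so it is no separate check from leaving out that library. Pairs of libraries within a group were checked for duplicates by a chi-square test, and the chi-square per degree of freedom ran from 2.97 to 102, so none was counted as a duplicate. Shares of reads and list levels were compared with exact permutation tests. Scripts ran in R 4.3.3 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.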

Results

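Gene expression was measured in the pancreas of 13 mice at 8 weeks of age: 3 wild type, 4 with Nrf2 active in pancreatic cells, 3 with mutant Kras and 3 with both changes (Kras+Nrf2). Libraries held 798347 to 1526628 assigned reads. Genes with at least 1 read numbered 9011 ± 316 (mean ± SD) in wild type and 14970 ± 2092 in Kras+Nrf2 pancreas. Reads outside acinar enzyme genes, Gm42418 and mitochondrial rRNA were 8.65% of assigned reads in wild type and 44.6% in Kras+Nrf2 libraries. The numbers of detected genes were not adjusted for that depth, so they cannot be read as a change in expression.

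The targeted genes were read first. Nfe2l2, which encodes NRF2 (ENSMUSG00000015839, GRCm38 chromosome 2, 75675513 to 75704641, minus strand), had 8.09, 11.9 and 10.6 normalised CPM in the wild-type libraries and 6.57, 2.64, 14.5 and 9.71 in the Nrf2-active libraries. It had 13.4, 6.49 and 6.44 in Kras-mutant and 20.9, 14.8 and 36.4 in Kras+Nrf2 libraries. The labels do not say how Nrf2 was activated, so Nfe2l2 RNA need not rise. Kras (ENSMUSG00000030265) had 21.03, 23.7 and 12.1 in wild type, 21.4, 24.6, 33.3 and 27.4 in Nrf2-active, 24.3, 35.7 and 27.1 in Kras-mutant and 27.8, 19.3 and 46.2 in Kras+Nrf2 libraries. A 3' tag cannot see a change at codon 12, so these values do not check the Kras genotype. Nqo1, a quinone reductase gene and a standard NRF2 target, had no read in any of the 10 libraries of the other 3 groups. In the Kras+Nrf2 libraries it had 5.51, 5.78 and 4.19 CPM, 64 reads in all. This was at least 3.36-fold the wild-type, 6.13-fold the Nrf2-active and 5.15-fold the Kras-mutant level, though Nqo1 had too few reads to be tested. Keap1, which encodes the NRF2 repressor, had 4.85, 7.41 and 10.6 in wild type, 8.22, 13.2, 8.69 and 15.0 in Nrf2-active, 7.28, 9.74 and 10.3 in Kras-mutant and 13.0, 8.34 and 9.69 in Kras+Nrf2 libraries. Ezh2, which encodes the histone H3K27 methyltransferase, had 4.85, 7.41 and 10.6 in wild type, 11.5, 7.04, 14.5 and 11.5 in Nrf2-active, 7.28, 9.74 and 13.5 in Kras-mutant and 18.2, 11.6 and 14.7 in Kras+Nrf2 libraries. Ezh2 in Kras+Nrf2 vs wild type had a log2 fold change of 0.84 (SE 0.40, limma adjusted p = 0.137), not past the test. On the deposited CPM without TMM it was 2.85 (limma adjusted p = 0.000491), on a scale where the median of all tested genes was 2.14, so that call came with a shift of most genes.

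The make-up of the libraries set the Kras+Nrf2 pancreas apart. Acinar enzyme genes took 45.7 ± 3.70% of assigned reads in wild type, 51.8 ± 6.07% in Nrf2-active, 50.3 ± 3.44% in Kras-mutant and 23.4 ± 19.2% in Kras+Nrf2 libraries. Kras+Nrf2 replicate 3 had 1.71%, and the highest of that group was 38.3%. Genes outside the acinar enzymes, Gm42418 and mitochondrial rRNA took 8.65 ± 0.484% in wild type and 44.6 ± 23.6% in Kras+Nrf2 libraries. The ratio of acinar to these other reads was 5.31 in wild type, 4.49 in Nrf2-active, 4.36 in Kras-mutant and 0.805 in Kras+Nrf2 libraries. Against wild type and against Kras-mutant pancreas the exact permutation p was 0.1, the smallest that 3 against 3 libraries can give. Against Nrf2-active pancreas the exact permutation p was 0.0286, or 0.167 adjusted over 35 tests. The median log2 fold change over all tested genes against wild type was 2.14 on the deposited CPM, where a smaller enzyme share leaves more reads for all other genes, and 0.13 after TMM.

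**Figure D1:**
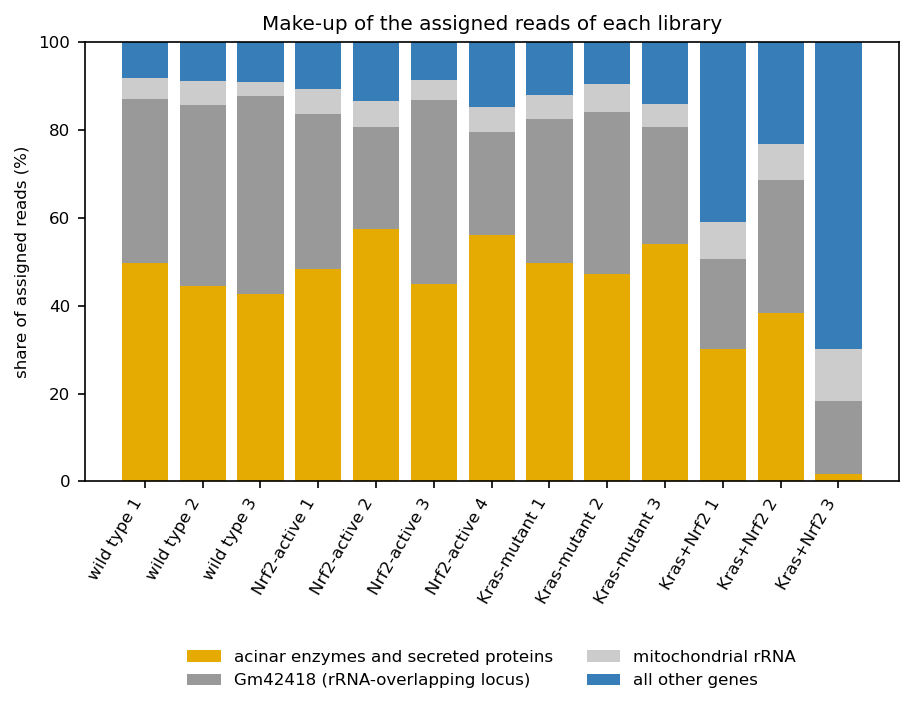
Share of assigned reads per library from acinar enzyme genes, Gm42418, mitochondrial rRNA and all other genes, in 13 libraries.

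Kras+Nrf2 vs wild type asked what the combination does to the pancreas. Spp1, which encodes the secreted ductal and macrophage protein osteopontin (ENSMUSG00000029304, GRCm38 chromosome 5, 104435118 to 104441050, plus strand), rose from 38.1 ± 10.6 to 453 ± 83.6 CPM (log2 fold change 3.48, SE 0.37, 3 mice per group). Ctss, which encodes the lysosomal protease cathepsin S of antigen-presenting cells, rose from 5.57 ± 2.18 to 183 ± 125 CPM (4.59, SE 0.50). Col3a1, a fibrillar collagen gene of fibroblasts, rose from 39.8 ± 10.9 to 422 ± 258 CPM (3.17, SE 0.47). Gclc, which encodes the catalytic subunit for the first step of glutathione synthesis, rose from 5.26 ± 5.30 to 49.2 ± 16.5 CPM (3.21, SE 0.51). Ctrc, which encodes the trypsinogen-degrading enzyme chymotrypsin C, fell from 314 ± 49.2 to 18.6 ± 17.7 CPM (−4.73, SE 0.59).

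In the macrophage list, 22 of 22 tested genes rose (median log2 fold change 3.39, camera adjusted p = 7.36e-16; adjusted p = 0.109 with an estimated correlation), among them Ctss, Apoe (3.43) and Ccr2 (4.33). In the fibroblast and matrix list, 19 of 26 rose and 7 were not past the test (2.60, camera adjusted p = 7.56e-11; adjusted p = 0.151 with an estimated correlation), and 20 rose when adjusted over the list alone. Col3a1, Col1a2 (3.84) and Bgn (4.79), a matrix proteoglycan gene, were among them. In the metaplasia list, 12 of 18 rose and 6 were not past the test (2.62, camera adjusted p = 3.39e-06; adjusted p = 0.109 with an estimated correlation). S100a11 (3.59, SE 0.46), a calcium-binding protein gene of early pancreatic lesions, led that list by limma p with S100a6 (3.01) and Ctse (at least 10.0-fold). Ctse encodes cathepsin E, and its call was lost with DESeq2. Tff2, the list gene with the most reads, was lower, at a mean of 2444 CPM in wild type and 691 in Kras+Nrf2 libraries. Adjusted over the list alone 13 metaplasia genes rose and 1 fell. Of 18 ductal genes, 9 rose and 9 were not past the test (1.42, camera adjusted p = 0.000211; adjusted p = 0.117 with an estimated correlation), among them Epcam (2.70), an epithelial adhesion gene, and Onecut2 (at least 48.7-fold), a ductal transcription factor gene. Adjusted over the list alone 9 ductal genes rose and 1 fell.

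NRF2 target genes were partly raised in the combined genotype. Of 27 tested, 13 rose, Gstm2 fell and 13 were not past the test (median 1.45, camera adjusted p = 0.000185; adjusted p = 0.129 with an estimated correlation). Adjusted over the list alone 14 rose and 1 fell. Those that rose were Gclc, Gpx2 (at least 12.0-fold), Gsta4 (4.61), Me1 (2.91), Mgst1 (2.89), Cbr3 (2.52), Srxn1 (2.46), Blvrb (2.44), Gsta3 (2.36), Prdx1 (2.27), Hmox1 (1.87), Txnrd1 (1.56) and Tkt (1.45). Gclm, which encodes the regulatory partner of Gclc, was not past the test (0.06), and neither was Sqstm1 (−0.29).

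Further lists also moved, each read from its tested genes alone. These were 16 of 42 inflammation, 7 of 40 cell cycle, 7 of 30 RAS and ERK output and 9 of 27 immediate early genes. Of 16 inflammation genes, 8 rose and 8 were not past the test (median 2.04, camera adjusted p = 0.000385; adjusted p = 0.109 with an estimated correlation), among them Lcn2 (3.90), a siderophore-binding protein gene, and Cxcl5 (at least 9.17-fold), a neutrophil chemokine gene. The inflammation level was 2.78, 2.81 and −0.13 log2 units from the wild-type mean in Kras+Nrf2 replicates 1, 2 and 3. The list mean thus did not rise in replicate 3, and the exact permutation p against wild type was 0.3. Single genes differed from that mean, since Cxcl5 and Lcn2 were higher in each Kras+Nrf2 library than in any wild-type library. The list was not past the test on the deposited CPM (camera adjusted p = 0.142). Of 7 cell cycle genes, 5 rose and 2 were not past the test (2.04, camera adjusted p = 0.000498; adjusted p = 0.109 with an estimated correlation), among them the proliferation marker Mki67 (at least 6.37-fold), and all 7 rose when adjusted over the list alone. Of 7 RAS and ERK output genes, 6 rose and 1 was not past the test (2.11, camera adjusted p = 0.000498; adjusted p = 0.129 with an estimated correlation), among them the membrane protein gene Emp1 (3.78), and all 7 rose when adjusted over the list alone. Of 9 immediate early and heat shock genes, 4 rose and 5 were not past the test (1.27, camera adjusted p = 0.0385; adjusted p = 0.257 with an estimated correlation). That list was lost in 5 alternatives, among them without wild type replicate 1 (camera adjusted p = 0.117).

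The acinar programme fell with the enzymes. Of 40 acinar enzyme genes, 27 fell and 13 were not past the test (median −4.01, camera adjusted p = 7.36e-16; adjusted p = 0.248 with an estimated correlation), and 35 fell when adjusted over the list alone. Cela3a, an elastase gene (−4.23), Pla2g1b, a phospholipase gene (−5.03), and Try10, a trypsinogen gene (−4.91), were among them. On the deposited CPM the median was −1.83. Of 19 genes of acinar transcription factors and secretory apparatus, 9 fell and 10 were not past the test (−1.51, camera adjusted p = 1.3e-05; adjusted p = 0.248 with an estimated correlation). Gnmt, a glycine methyltransferase gene (−3.26), and Bhlha15, which encodes the acinar factor MIST1 (−2.21), were among them. Of 27 genes of the unfolded protein and integrated stress response, 21 fell and 6 were not past the test (−1.67, camera adjusted p = 1.33e-09; adjusted p = 0.158 with an estimated correlation). On the deposited CPM the medians of the last 2 lists were 0.37 and 0.43, above 0, though single genes such as Gnmt (−1.41) stayed lower there. Acinar enzyme levels in the Kras+Nrf2 libraries were −2.79, −1.73 and −7.29 log2 units from the wild-type mean, whereas macrophage levels were 3.20, 3.05 and 4.11. Levels of acinar factors and secretory apparatus were −1.19, −0.62 and −3.17, and those of the unfolded protein and stress response −1.13, −0.87 and −2.54, so replicate 3 carried much of these falls.

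Islet genes were not past the test (0 of 13 past the gene test, camera adjusted p = 0.394), nor were endothelial genes (0 of 8, camera adjusted p = 0.68). Median, mean and test direction disagreed for glycolysis (median 0.19, mean 0.06, down), adipocytes (−0.27, 0.29, up), hepatocytes (−1.21, 0.15, down) and lysosome (−0.24, 0.11, down). None of these 4 was past the test (camera adjusted p = 0.99 for each).

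**Figure D2:**
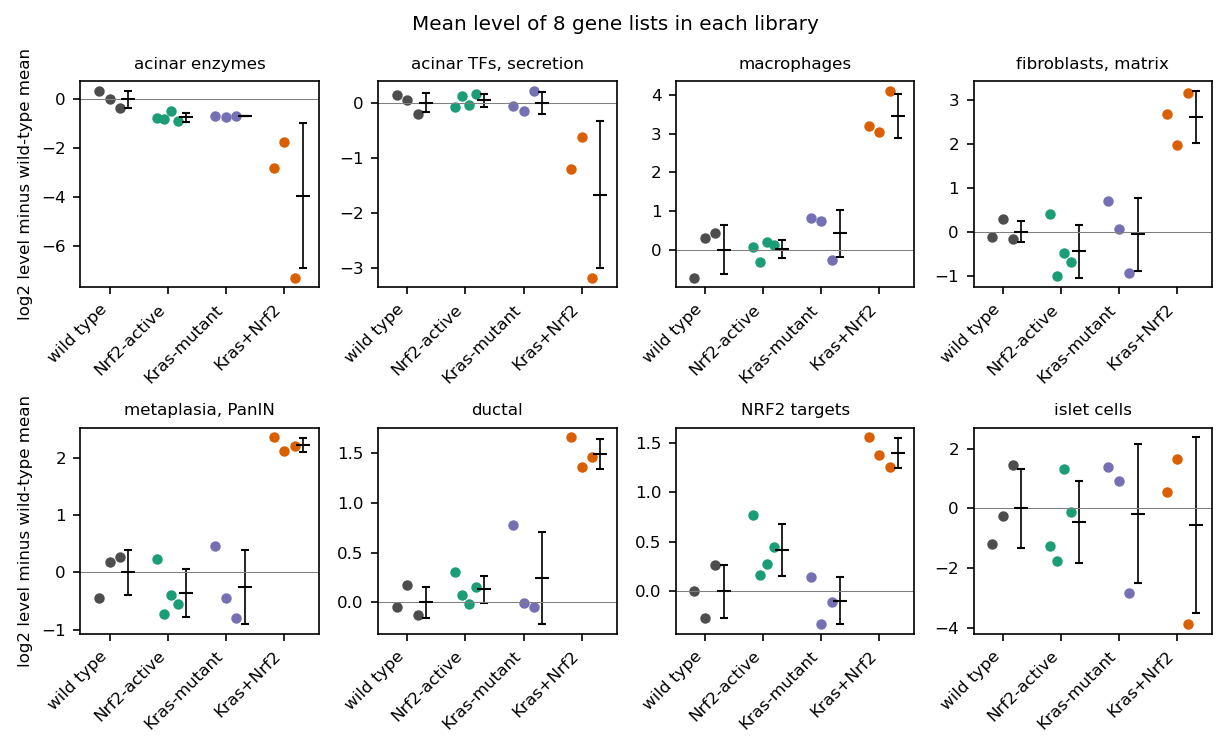
Mean log2 level of 8 gene lists per library relative to the wild-type mean. Bars give mean ± SD of each genotype.

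In all, limma placed 1078 of 4635 genes past the test in Kras+Nrf2 vs wild type, 578 higher and 500 lower. The edgeR test gave 1037 and DESeq2 933. On the deposited CPM without TMM there were 3796, 3741 higher and 55 lower, so the division between higher and lower rests on the scaling. In the 9 low-numbered libraries there were 579, 285 higher and 294 lower. Leaving out Kras+Nrf2 replicate 3 gave 573, and leaving out wild type replicate 1 gave 691.

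Kras+Nrf2 vs Kras-mutant asked what active Nrf2 adds to mutant Kras. S100a11 rose from 3.42 ± 2.34 to 84.1 ± 19.9 CPM (log2 fold change 4.34, SE 0.46, 3 mice per group). Gsta3, a glutathione transferase gene, rose from 3.85 ± 2.22 to 36.2 ± 12.2 CPM (2.98, SE 0.43), and Gsta4, which encodes a transferase for lipid peroxidation products, had no read in Kras-mutant libraries and rose at least 43.0-fold. Sfrp1, a secreted WNT antagonist gene, rose from 3.04 ± 1.24 to 160 ± 164 CPM (4.83, SE 0.67), with 84.9, 46.9 and 348 CPM in the 3 libraries. Ctrc fell from 190 ± 37.1 to 18.6 ± 17.7 CPM (−3.95, SE 0.59).

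In Kras+Nrf2 vs Kras-mutant, 22 of 22 macrophage genes rose (median 3.02, camera adjusted p = 1.94e-16; adjusted p = 0.0871 with an estimated correlation), among them Ctss (3.97), C1qb (3.54) and Apoe (2.98). Of 26 matrix genes 19 rose and 7 were not past the test (2.75, camera adjusted p = 2.2e-14; adjusted p = 0.129 with an estimated correlation). Of 18 metaplasia genes 13 rose and 5 were not past the test (3.20, camera adjusted p = 1.59e-08; adjusted p = 0.0871 with an estimated correlation). Of 27 NRF2 target genes 12 rose, 1 fell and 14 were not past the test (1.30, camera adjusted p = 2.66e-06; adjusted p = 0.102 with an estimated correlation), and 13 rose and 1 fell when adjusted over the list alone. Gpx2, a gut-type glutathione peroxidase gene, rose at least 18.3-fold. Of 18 ductal genes 7 rose, 1 fell and 10 were not past the test (1.26, camera adjusted p = 0.000602; adjusted p = 0.131 with an estimated correlation), with Spp1 at 2.61. Of 7 interferon response genes 2 rose, B2m (2.34) and Psmb8 (2.79), both of antigen presentation (median 1.78, camera adjusted p = 0.0213; adjusted p = 0.176 with an estimated correlation), and the list was lost without Kras+Nrf2 replicate 2 (camera adjusted p = 0.094).

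Acinar enzymes fell here as well, 14 of 40 with 26 not past the test (median −3.53, camera adjusted p = 1.1e-13; adjusted p = 0.251 with an estimated correlation), and 32 fell when adjusted over the list alone. Of 27 genes of the unfolded protein and integrated stress response 18 fell and 9 were not past the test (−1.71, camera adjusted p = 6.51e-12; adjusted p = 0.131 with an estimated correlation), with a median of −0.07 on the deposited CPM. Of 19 acinar factor and secretory genes 7 fell and 12 were not past the test (−1.77, camera adjusted p = 1.57e-06; adjusted p = 0.176 with an estimated correlation), with Gnmt at −2.96. Another 4 lists were higher. Of 16 inflammation genes 7 rose and 9 were not past the test (1.74, camera adjusted p = 0.000343; adjusted p = 0.102 with an estimated correlation), though not on the deposited CPM (camera adjusted p = 0.092). The list level of Kras+Nrf2 replicate 3, at −0.13, lay below Kras-mutant replicates 1 and 2 (0.93 and 0.78). The rise in list level thus came from Kras+Nrf2 replicates 1 and 2, though Cxcl5 and Lgals3 were higher in all 3 Kras+Nrf2 libraries. RAS and ERK output (2 of 7 rose, 1.76, camera adjusted p = 0.00222), immediate early genes (4 of 9, 1.36, 0.005) and cell cycle (2 of 7, 1.46, 0.00924) passed as well, each at adjusted p = 0.136 with an estimated correlation. Nfe2l2 itself was not past the limma test (log2 fold change 1.31, SE 0.50, adjusted p = 0.0788). The limma total was 761 genes, 419 higher and 342 lower, against 885 with edgeR and 827 with DESeq2. On the deposited CPM it was 2843, 2778 higher and 65 lower. The low-numbered libraries gave 300, the compared groups alone 381, and the fit without Kras-mutant replicate 2, Kras-mutant replicate 3 or Kras+Nrf2 replicate 3 gave 413, 483 and 440.

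Kras+Nrf2 vs Nrf2-active asked what mutant Kras adds to active Nrf2. Sfrp1 rose from 0.881 ± 1.24 to 160 ± 164 CPM (log2 fold change 6.11, SE 0.63, 3 and 4 mice). Ccl8, a monocyte chemokine gene, had no read in the Nrf2-active libraries and rose at least 48.2-fold, and Ccl6, another myeloid chemokine gene, rose (4.81, SE 0.51). Fn1, which encodes fibronectin, rose (4.72, SE 0.79), and Ctrc fell (−4.60, SE 0.55). Gstm2, a glutathione transferase gene on the NRF2 target list, fell (−2.17, SE 0.34).

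In Kras+Nrf2 vs Nrf2-active, 22 of 22 macrophage genes rose (median 3.38, camera adjusted p = 1.48e-18; adjusted p = 0.0452 with an estimated correlation), with C1qa at 4.49. Of 18 metaplasia genes 14 rose and 4 were not past the test (2.85, camera adjusted p = 2.93e-09; adjusted p = 0.0452 with an estimated correlation). Of 16 inflammation genes 8 rose and 8 were not past the test (3.63, camera adjusted p = 3.94e-08; adjusted p = 0.0442 with an estimated correlation). The inflammation level of Kras+Nrf2 replicate 3 (−0.13) was far nearer the Nrf2-active mean (−1.28) than those of replicates 1 and 2 (2.78 and 2.81). The macrophage, metaplasia and inflammation lists were the only ones of any comparison that stayed past the test when the correlation was estimated. Of 26 matrix genes 22 rose and 4 were not past the test (3.07, camera adjusted p = 3.72e-17; adjusted p = 0.0961 with an estimated correlation). Of 7 RAS and ERK output genes 5 rose and 2 were not past the test (2.38, camera adjusted p = 0.000127; adjusted p = 0.0961 with an estimated correlation), among them Ccnd1 (3.19), the cyclin D1 gene. Of 27 NRF2 targets 10 rose, Gstm2 fell and 16 were not past the test (0.91, camera adjusted p = 0.00272; adjusted p = 0.198 with an estimated correlation). Of 40 acinar enzymes 20 fell and 20 were not past the test (−3.51, camera adjusted p = 2.16e-13; adjusted p = 0.28 with an estimated correlation). Of 27 unfolded protein and integrated stress response genes 19 fell (−1.70, camera adjusted p = 1.24e-10; adjusted p = 0.145 with an estimated correlation), and of 19 acinar factor and secretory genes 9 fell (−1.61, camera adjusted p = 1.24e-06; adjusted p = 0.209 with an estimated correlation). Ductal genes (7 of 18 rose, 1.07, camera adjusted p = 0.000139; adjusted p = 0.0961 with an estimated correlation) and cell cycle genes (3 of 7, 1.83, camera adjusted p = 0.00455; adjusted p = 0.114 with an estimated correlation) passed upward. Immediate early genes did so at the edge (2 of 9, 0.98, camera adjusted p = 0.0357; adjusted p = 0.271 with an estimated correlation) and were lost in 6 alternatives.

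Nfe2l2 rose in this comparison alone (log2 fold change 1.48, SE 0.47, limma adjusted p = 0.0305). The call on Nfe2l2 was lost in 8 alternatives, for example in the low-numbered libraries (0.61, limma adjusted p = 0.536) and without Kras+Nrf2 replicate 3 (1.11, limma adjusted p = 0.171). The limma total was 873 genes, 484 higher and 389 lower, against 1046 with edgeR and 987 with DESeq2. On the deposited CPM it was 2986, 2907 higher and 79 lower. The low-numbered libraries gave 360, and leaving out Kras+Nrf2 replicate 3 gave 528.

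**Figure D3:**
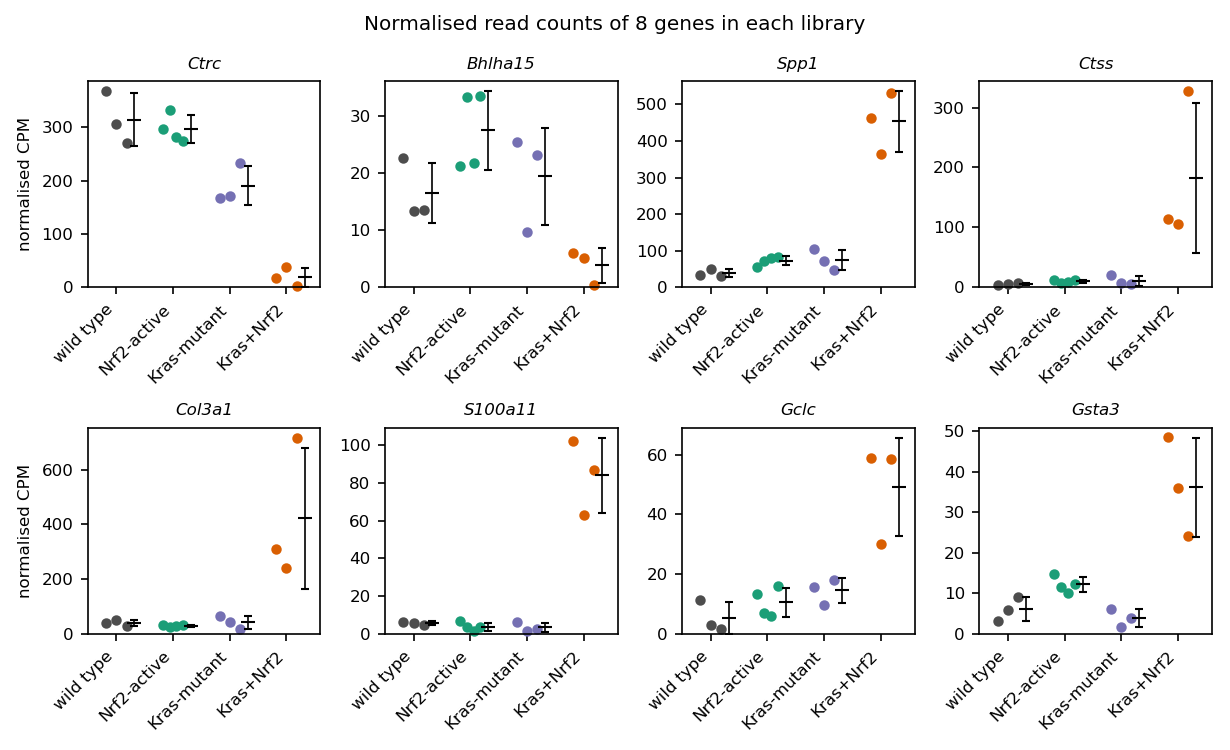
Normalised CPM of 8 genes in each of the 13 mice. Bars give mean ± SD of each genotype.

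Nrf2-active vs wild type and Kras-mutant vs wild type asked what each change does alone. No gene passed the limma test in either. For Nrf2, 334 genes had a raw limma p below 0.05, edgeR gave 0 and DESeq2 3. The 3 DESeq2 genes were the trypsinogen genes Gm5771 (−4.78), Prss1 (−5.64) and Prss3 (−3.48), chosen after their values were seen. Gm5771 had 12770, 4435 and 511 CPM in the wild-type libraries, so this difference rested mainly on wild type replicates 1 and 2. For Kras, 386 genes had a raw limma p below 0.05, edgeR gave 0 and DESeq2 4, the same 3 genes and Lrrc17 (−3.03), a leucine-rich repeat protein gene. Lrrc17 was the closest to the limma test (−2.59, SE 0.45, limma adjusted p = 0.0537). Gstm1, a glutathione transferase gene, had 15.9 ± 3.13 CPM in wild type and 45.7 ± 15.0 in Nrf2-active libraries (1.37), not past the test.

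For Nrf2-active vs wild type, 5 lists passed camera although no member gene passed its own test, and none passed with an estimated correlation or with fry. NRF2 targets had a median log2 fold change of 0.39 with 22 of 27 positive (camera adjusted p = 0.0132; adjusted p = 0.709 with an estimated correlation). Leaving out wild type replicate 2 (camera adjusted p = 0.424) or Nrf2-active replicate 1 (0.179) ended that call. Acinar enzymes had a median of −0.41 in 40 genes (camera adjusted p = 0.00679; adjusted p = 0.973 with an estimated correlation), and with a term for the title numbers the direction turned up (camera adjusted p = 0.988). Of these 40 genes 1 fell when adjusted over the list alone. On the deposited CPM the acinar median was 0.17, above 0, where the median of all tested genes was 0.51. Matrix genes had a median of −0.50 (camera adjusted p = 0.00679; 0.728 as adjusted p with an estimated correlation), inflammation −0.73 (0.00679; 0.566) and red blood cell genes −1.36 (0.00679; 0.709), and each of these 3 was lost in at least 2 alternatives. For Kras-mutant vs wild type, 2 lists passed camera: acinar enzymes (median −0.43, camera adjusted p = 0.0136; adjusted p = 0.911 with an estimated correlation) and red blood cells (−2.11, camera adjusted p = 0.0136; adjusted p = 0.911 with an estimated correlation). In Nrf2-active vs wild type the median and mean differed in sign for 9 of the 25 lists tested with camera, none of them past it. They were ductal (−0.05 and 0.13), Polycomb (−0.19 and 0.03), endothelial (0.04 and −0.05), macrophage (−0.07 and 0.02), tumour suppressor (−0.01 and 0.06), RAS and ERK output genes (−0.16 and 0.00), acinar factors (−0.07 and 0.04), unfolded protein response (0.07 and −0.02) and adipocytes (0.25 and −0.00003). In the Kras-mutant comparison acinar enzymes were lost without wild type replicate 1 (camera adjusted p = 0.165), and red blood cells without wild type replicate 3 (0.26). The acinar median of that comparison was 0.08 on the deposited CPM, where the median of all tested genes was 0.46.

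The interaction asked whether the effect of Nrf2 differed with Kras status. Limma placed 201 genes past the test, 131 higher and 70 lower, against 112 with edgeR and 203 with DESeq2. S100a11 (log2 interaction 4.96, SE 0.64, limma adjusted p = 0.000366) and the actin-binding peptide gene Tmsb4x (4.46, SE 0.56, limma adjusted p = 0.000366) had the smallest p. Sfrp1 (6.14, SE 0.92, limma adjusted p = 0.00239) and Lgals3, which encodes galectin-3 (5.36, SE 0.85, limma adjusted p = 0.00407), followed. Lgals3 had few reads outside the Kras+Nrf2 libraries, at 3.06 CPM in wild type and 0.411 in Nrf2-active libraries. Of 26 matrix genes 11 were past the interaction test upward (median 3.42, camera adjusted p = 3.38e-17; adjusted p = 0.101 with an estimated correlation), as were 12 of 22 macrophage genes (2.90, camera adjusted p = 1.84e-15; adjusted p = 0.0724 with an estimated correlation) and 8 of 18 metaplasia genes (3.72, camera adjusted p = 9e-10; adjusted p = 0.0556 with an estimated correlation). Of 27 NRF2 targets 5 were past it upward and 1 downward (0.79, camera adjusted p = 0.00161; adjusted p = 0.226 with an estimated correlation). Of 40 acinar enzymes 1 was past it downward (−3.12, camera adjusted p = 5.41e-07; adjusted p = 0.418 with an estimated correlation). The total was 51 in the low-numbered libraries, 42 with no filter and 403 on the deposited CPM (390 higher, 13 lower). Single libraries moved it from 78 without wild type replicate 3 to 351 without Kras+Nrf2 replicate 2. Across all tested genes, the Nrf2 effect with mutant Kras and without it had a Pearson correlation of 0.104, and the Kras effect with active Nrf2 and without it 0.167.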

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

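The tests chosen after the result was seen were the deposited CPM for Slc35c2, the share of calls kept without Kras+Nrf2 replicate 3, the gaps between list levels, the use of the simulated recoveries, the title-number tests, and the estimated correlation as a test of the acinar enzyme list.

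The interaction was past the limma test in 201 genes, and 27 of the named genes were among them. Those higher were Tmsb4x (4.46), S100a11 (4.96), Sfrp1 (6.14), Lgals3 (5.36), Col3a1 (3.79), Ccl8 (5.10), S100a6 (3.54), Timp1 (3.90), Car2 (4.40), Cxcl5 (3.85), C1qb (3.88), Col1a2 (4.42), Ctse (3.90), Ctss (3.25), Gsta4 (4.32), Junb (4.01), Apoe (2.72), Gpx2 (3.39), B2m (2.06) and Il33 (3.07). Those lower were Slc35c2 (−2.86), Vldlr (−2.75), Ctrc (−3.82), Bhlha15 (−2.98), Gnmt (−2.74), Mthfd2 (−2.28) and Chac1 (−2.59). Slc35c2, a transporter-family gene, was not past the test on the deposited CPM (−1.91, limma adjusted p = 0.0974). Timp1, Cxcl5 and Ctse had no read outside the Kras+Nrf2 libraries. Their interaction values therefore repeat those of Kras+Nrf2 vs Kras-mutant, and an effect of Nrf2 without mutant Kras could not be measured for them. Lgals3 and Car2 also had few reads, at 3.06 and 1.54 CPM in wild type and 0.411 and 0.220 in Nrf2-active libraries. Their interaction values exceed those of Kras+Nrf2 vs Kras-mutant (3.74 and 3.25) through that small difference in reads.

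Of the lists, 13 differed in the interaction by camera. Median log2 interactions were 0.79 for NRF2 targets, −3.12 for acinar enzymes, −1.89 for acinar factors and secretory apparatus, 0.92 for ductal, 3.72 for metaplasia, 3.42 for matrix and 2.90 for macrophage genes. They were 3.47 for red blood cell, 1.27 for immediate early, −1.63 for unfolded protein and stress response, 2.17 for RAS and ERK output, 2.86 for inflammation and 1.97 for interferon genes. None of the 13 was past the test with an estimated correlation. Directional fry kept 9 lists and lost acinar enzymes (fry adjusted p = 0.185), acinar factors (0.0891), red blood cell (0.0891) and interferon genes (0.062). The mean level of the inflammation list rose in Kras+Nrf2 replicates 1 and 2 (2.78 and 2.81) but not in replicate 3 (−0.13). Single genes such as Cxcl5 were raised in replicate 3 as well.

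Other labels were put on the libraries to see how many genes they would give. For Nrf2-active vs wild type 35 of 35 splits gave at least the real 0, and another split gave at most 1. For Kras-mutant vs wild type 10 of 10 did, and the highest other split gave 0. Any split reaches a real count of 0, so for the single genotypes these shares were fixed in advance and say nothing about chance. For Kras+Nrf2 vs wild type only the real split of 10 reached 1078 (1 of 10, highest other 0), and for Kras+Nrf2 vs Kras-mutant only the real split of 10 reached 761 (1 of 10, highest other 1). With 10 splits no share below 5% is possible. For Kras+Nrf2 vs Nrf2-active 1 of 35 splits reached 873, and the highest other gave 129. For the interaction 3 of 100 drawn labellings reached 201, the highest other giving 215. That labelling kept the Kras+Nrf2 libraries together and exchanged wild type replicate 2 with Nrf2-active replicate 1.

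Dixon's test for a library apart from its group was run in the Nrf2-active libraries only, on 63 named genes and library measures. It found 3, all of them genes. They were Top2a (11.5 CPM) and Cd44 (16.4 CPM) in Nrf2-active replicate 1 and Il33 (4.35 CPM) in Nrf2-active replicate 3. Such a test finds about 1 in 20 by chance, and 3 of 63 is near that number.

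Reads outside annotated genes were not analysed further. Their share passed the highest wild-type value of 10.9% in Nrf2-active replicates 2, 3 and 4 (11.8%, 11.0% and 12.3%), Kras-mutant replicate 3 (13.2%) and Kras+Nrf2 replicates 1, 2 and 3 (17.9%, 12.7% and 37.4%). The cause was not tested.

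Of the rises and falls in Kras+Nrf2 pancreas against wild type, 51.8% of the genes stayed called without Kras+Nrf2 replicate 3, so that library was not the whole cause. A single scaling factor per library was excluded as the whole cause, since macrophage minus acinar level in the lowest Kras+Nrf2 library lay 3.29 log2 units above the highest of the other 10. Fewer acinar cells would raise all other cell types alike, but macrophage minus endothelial level in the lowest Kras+Nrf2 library lay 1.31 above the highest of the other 10 (SD 0.502), which excludes this as the whole cause. Macrophage minus islet level did not separate the groups, at −1.19 by the same measure with an SD of 1.17, as islet levels varied widely between libraries. Fewer acinar cells as a part of the cause and a biological difference in the macrophages and other cells that rose stay open, the latter untested.

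The absence of limma calls in Nrf2-active vs wild type was weighed against power and title numbers. Only 10.4% of simulated 2-fold changes were recovered, so changes of that size could be present and missed. Of simulated 8-fold changes 87.9% were recovered, but larger observed differences between group means stayed uncalled. Reg2 had a mean of 4327 normalised CPM in wild type and 56.1 in Nrf2-active libraries. Gm5771 had a log2 fold change of −4.26 (limma adjusted p = 0.570), with 12770, 4435 and 511 CPM in the wild-type libraries. Whether these differences are true changes was not shown. The simulated recovery therefore cannot say how many real changes of that size were missed. With a title-number term limma called 0 genes, which leaves open whether spread between these classes hid small changes, since their recovery was low.

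After TMM the acinar enzyme list was lower in all 4 Nrf2-active libraries (−0.90 to −0.47) than in the 3 wild-type ones (−0.35 to 0.34). The exact permutation p was 0.0286, the smallest possible, and the median log2 fold change was −0.41. On the deposited CPM that median was 0.17, where all tested genes had a median of 0.51. The acinar share of reads was 51.8% in Nrf2-active and 45.7% in wild type. The sign of this difference thus rests on the scaling. Without the trypsinogen genes, whose median was −1.90, the other 30 kept a median of −0.27 with a camera p of 0.157, so these related genes carried part of the fall. With an estimated correlation the raw camera p was 0.479, so the camera call rested on treating the genes as nearly independent. For the title numbers, the lowest wild-type level lay 0.113 log2 units above the highest of the low-numbered Nrf2-active libraries, less than the wild-type SD, which leaves that explanation undecided. With the title-number term in Nrf2-active vs wild type the direction turned up (camera adjusted p = 0.988).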

How the results depend on the processing

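The edgeR test, the deposited CPM without TMM, scaling without rRNA, the pseudocounts of 0.5 and 4, the title-number term, the low-numbered libraries alone and the exclusion of Kras+Nrf2 replicate 3 with wild type replicate 3 were added after the data were seen. The other alternatives were planned. Why a count moved was not tested unless stated.

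For Nrf2-active vs wild type the total of 0 genes became 3 with DESeq2 and 1 in the compared groups only. Leaving out single libraries gave 0 (for example wild type replicate 2) to 2 (wild type replicate 3). For Kras-mutant vs wild type the total of 0 became 4 with DESeq2, 2 in the compared groups only, 2 with a pseudocount of 4 and 1 with the title-number term. With 1 library left out at a time the total ran from 0 (for example wild type replicate 2) to 4 (wild type replicate 3).

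For Kras+Nrf2 vs wild type the total of 1078 became 1700 with no filter, 3796 on the deposited CPM without TMM, 579 in the low-numbered libraries and 416 without the 2 libraries apart. Single libraries left out gave 573 (Kras+Nrf2 replicate 3) to 1232 (Kras+Nrf2 replicate 2). For Kras+Nrf2 vs Kras-mutant the total of 761 became 1192 with no filter, 381 in the compared groups only, 2843 on the deposited CPM, 300 in the low-numbered libraries and 404 without the 2 libraries apart. Leaving out single libraries gave 413 (Kras-mutant replicate 2) to 843. For Kras+Nrf2 vs Nrf2-active the total of 873 became 1559 with no filter, 2986 on the deposited CPM, 360 in the low-numbered libraries and 515 without the 2 libraries apart. With 1 library left out at a time the total ran from 528 (Kras+Nrf2 replicate 3) to 960.

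The 201 genes of the interaction became 119 without acinar enzymes in the libraries, 42 with no filter, 112 with edgeR, 403 on the deposited CPM, 110 with a pseudocount of 0.5 and 373 with a pseudocount of 4. The title-number term gave 367, the low-numbered libraries 51 and the exclusion of the 2 libraries apart 62. Single libraries left out gave 78 (wild type replicate 3) to 351 (Kras+Nrf2 replicate 2).

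For gene lists in Nrf2-active vs wild type, the 5 past camera became 0 with an estimated correlation, 0 with fry, 0 with fry in its mixed form, 9 on the deposited CPM, 1 with the title-number term and 3 in the low-numbered libraries. Leaving out single libraries gave 2 (wild type replicate 2) to 9 (wild type replicate 1). For Kras-mutant vs wild type the 2 lists became 0 with an estimated correlation, 0 with fry, 1 without acinar enzymes in the libraries, 0 with the title-number term and 5 in the low-numbered libraries. Fry in its mixed form and the deposited CPM each gave 3. With 1 library left out at a time the total ran from 1 (wild type replicate 1) to 4 (Kras-mutant replicate 3). With an estimated correlation the 12 lists of Kras+Nrf2 vs wild type and the 13 of Kras+Nrf2 vs Kras-mutant became 0. The 12 of Kras+Nrf2 vs Nrf2-active became 3 and the 13 of the interaction 0. Directional fry gave 16, 16, 15 and 9 lists in the same order, and its mixed form 18, 18, 18 and 15. Single libraries left out gave 11 to 13, 12 to 14, 12 to 12 and 11 to 13.

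Over all named genes and alternatives, 3326 results kept their direction and side of the test, 131 were no longer past it, 14 came past it and 1 turned direction. That 1 was Keap1 in Kras+Nrf2 vs Nrf2-active, at −0.12 in the reported fit and 1.38 on the deposited CPM without TMM. The median over all tested genes there was 1.57, so this turn came with a shift of most genes and says nothing about Keap1 itself. Calls on Timp1 and Ctse in Kras+Nrf2 vs wild type were lost with DESeq2 (adjusted p = 0.35 for each). The fall of Bhlha15 in that comparison was −0.57 on the deposited CPM.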

Other observations

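Genes of senescence and tumour suppression were read apart from the lists past their test. Cdkn2a, which encodes the cell cycle inhibitors p16 and p19, had no read in the 10 libraries of the other 3 groups and 6.63 ± 6.60 CPM in Kras+Nrf2 libraries, too few to be tested. Cdkn1a, which encodes the inhibitor p21, rose in Kras+Nrf2 vs wild type (log2 fold change 2.83, limma adjusted p = 0.0018), as did Igfbp7 (2.88), a secreted senescence-linked gene. The list as a whole was not past the test (camera adjusted p = 0.33, 2 of 12 rose). Saa3, an acute-phase gene of macrophages and epithelium, had no read elsewhere and 5.57 ± 2.20 CPM in Kras+Nrf2 libraries.

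The duct cytokeratin gene Krt19 rose in Kras+Nrf2 vs wild type (2.96, limma adjusted p = 0.0044) and so did the ductal factor gene Sox9 (1.23, limma adjusted p = 0.039). Of 7 genes of Polycomb repressive complex 2, the partner gene Mtf2 alone rose there (camera adjusted p = 0.394 for the list). S100a8, a neutrophil gene, and Thy1, a gene of T cells and fibroblasts, were the single tested members of their lists, at 4.05 and 2.95 in that comparison.

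Insulin genes varied by library more than by genotype. Ins2 had 3.95 deposited CPM in Kras+Nrf2 replicate 3 and 16.1 in Kras-mutant replicate 3, against 980 and 1131 in Kras+Nrf2 replicates 1 and 2. Ins1 and Gcg were low in the same 2 libraries (0.658 and 3.29 CPM, 4.68 and 6.02 CPM). How much islet tissue each sample held was not tested.

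The title numbers went with a gene pattern of their own. With them as a term in the fit, 295 genes were past the limma test, 111 higher and 184 lower in the libraries numbered 36 and above. The noncoding RNA gene Kcnq1ot1 (2.09) was higher, and the ribosomal protein gene Rpl12 (−1.73) lower, both chosen after their values were seen. The cause was not tested.

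The first 3 principal components of the log2 values held 43.5%, 12.5% and 7.99% of the variance. Reads of Xist and of Y-linked genes divided the mice by sex within every group, so sex did not follow genotype. Haemoglobin gene Hbb-bs varied widely within groups, at 203 ± 202 CPM in wild type and 238 ± 274 CPM in Kras+Nrf2 libraries.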
